A study of Mus musculus with 8 samples.

How the data were processed

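Gene expression was measured in C10, a mouse pre-B cell line derived from HAFTL that carries an inducible form of the transcription factor C/EBPα. A line with a control short hairpin RNA and a line labelled Tet2 knockdown were each sampled before induction (0 h) and after 24 h of induction with estradiol (100 nM) together with M-CSF and IL-3 (each at 10 ng/ml). Each of the 4 groups held 2 arrays, which the series design calls technical duplicates, so there were 8 arrays. The p-values therefore measure the spread between duplicate arrays and not between cultures, and no culture-to-culture error could be given.

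Per the labels, 500 ng of total RNA per sample was amplified and labelled with Cy3 by in vitro transcription. Per the file headers, the arrays were 1-colour Agilent mouse arrays of design 026655, annotated on mouse genome build mm9 (NCBI 37), and were extracted with Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09. The deposited scanner files hold each spot's intensity as a processed signal, which per the file headers was background-subtracted and detrended with no scaling between arrays, together with the raw mean intensity and the local background intensity. The deposited value table holds log2 values with the same distribution in every column, and the column median was 6.84 on every array. The authors' notes name limma without a version and do not state the background correction or the normalization. The table was matched by a recomputation from the mean signal with the normexp correction (offset 50) and quantile normalization, with a correlation across spots of at least 0.999999 on each array.

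Each array had 44397 features, of which 1377 were control spots and 43020 carried probes. Between 47.4% and 55.6% of the probe spots per array were well above background by the scanner software's own mark, 155 to 219 spots per array were marked as outliers and left out, and no spot was saturated. The 75th percentile of the processed signal ranged from 722 to 1435 intensity units. The number of arrays limits the precision of every value.

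The values analysed were log2 of the processed signal minus the log2 of the array's 75th percentile over non-control spots. Spots of one probe were averaged. A probe was kept if it was well above background on both arrays of at least 1 of the 4 groups, and the kept probe with the highest mean stood for its gene. This gave 20304 probes and 16152 genes, of which 12728 had 1 kept probe and 3424 had several. Gene names were taken from the reference table by accession for 11618 genes, by symbol for 580 and by synonym for 91, and 3863 kept the name in the file. Among the genes called in the control induction, 975 had another kept probe, and for 13 of these that probe was called in the opposite direction. The corresponding values were 12 of 1123 in the induction of the line labelled knockdown, 0 of 38 at 0 h, 0 of 45 at 24 h and 0 of 88 for the difference between the inductions. No probe sequences were searched against a genome, so probes shared between related genes were not excluded.

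One linear model with 4 group means was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), with 4 residual degrees of freedom and 1.51 prior degrees of freedom. The median standard error was 0.10 on the log2 scale for a comparison of 2 groups and 0.14 for the difference between the inductions. The 5 contrasts were the induction in each line, the line labelled knockdown against control at 0 h and at 24 h, and the difference between the inductions (the interaction). A gene was called where the Benjamini-Hochberg adjusted p over all 16152 genes was under 0.05 and the change was at least 2-fold. All tests were 2-sided. The ± values are standard errors of the fit unless SD is stated, and each group mean has n = 2 arrays.

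Where no array of one group was well above background, the fold is given as a lower bound. The bound compares the measured group with the other group after each array value was raised to the lowest value found well above background on that array. Genes with no array well above background in either group of a comparison get no fold. For the interaction no bound exists, and values of genes with a dim group are fitted values.

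Gene lists fixed in advance (29 lists) were tested with camera in limma with a preset inter-gene correlation of 0.01 and again with an estimated correlation, each adjusted over the 29 lists of a contrast. Of the lists' members, 621 were tested, 124 were on the array and filtered out, and 5 were not matched. The lists covered myeloid surface receptors, neutrophil and monocyte granule proteins, lysosome and phagosome, the NADPH oxidase complex, myeloid transcription factors, B lineage transcription factors, pre-B receptor and B cell signalling, MHC class II presentation, chemokines and cytokines, the interferon response, adhesion with integrins and the actin cytoskeleton, the S phase, the G2 and M phases, cell cycle inhibitors and p53 targets, MYC and ribosome biogenesis, DNA methylation enzymes, Polycomb and histone modifiers, cholesterol synthesis, lipid handling, glycolysis and hypoxia, the unfolded protein and amino acid response, heat shock and oxidative stress, and NF-kappaB targets. Further lists held markers of T cells, erythroid cells and megakaryocytes, dendritic cells, stem and progenitor cells, and stromal cells, and reference genes.

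The genes named were Tet2, the 10 genes with the highest and the 10 with the lowest change among called genes with an official-looking symbol in each contrast, up to 4 tested members of each list with the largest absolute change, and Actb and Gapdh, and the text names a part of the genes this rule selects. Of those not named, 2 are not reported here. For the interaction they also included the 10 lowest and 10 highest called values among genes called higher in the control induction. The comparisons, the calls, the lists, this rule and the alternatives, other than those said below to be added, were chosen before the data were examined.

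The replicate number matched the slide per the file headers, with every group on both slides. The deviations of replicate 1 from its group mean correlated across genes between all pairs of groups, with r from 0.298 to 0.413, so the replicate numbers paired the arrays, and a fit with the slide as a block was run as an alternative. Blocked values are given where they changed a call.

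The procedure was tested on simulated data with the measured spread and 16152 genes. For the comparison at 24 h, 0%, 28%, 70% and 92% of genes changed by 1.5-fold, 2-fold, 3-fold and 8-fold were recovered, with 1 false call. For the interaction the shares were 0%, 22%, 64% and 82%, with 2 false calls. Since a call needed a change of at least 2-fold, that minimum itself limited the shares at 1.5-fold and 2-fold. A comparison with no simulated change gave 0 calls.

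The alternatives were normexp correction with percentile scaling, normexp with quantile normalization, quantile normalization of the processed signal, median scaling, the deposited value table, no filter on dim probes, a filter on all 8 arrays, outlier spots kept, the mean of a gene's probes, variance moderation with trend and robust set, the slide as a block, each slide alone, averaged duplicates, other fold minimums, limma treat against 1.5-fold, and each array left out in turn. A floor on dim signals and counts outside the interferon list were added after the data had been seen. With 2 arrays per group, no array could be tested as an outlier within its group, and no other splits of the arrays were counted.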

Results

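Gene expression was profiled in a control line and a line labelled Tet2 knockdown of C10, a pre-B cell line in which an inducible C/EBPα switches cells towards a macrophage-like state. The 4 groups were control cells at 0 h, control cells at 24 h, and the line labelled knockdown at 0 h and at 24 h, with n = 2 arrays in each. Induction set the arrays apart far more than the label of the line did. The first principal component held 85.3% of the variance and separated 0 h from 24 h, while the next held 4.16%. Duplicate arrays correlated across genes with r from 0.992 to 0.994. Between the duplicates of a group, 557 to 693 of the 16135 to 16148 genes with a value on both arrays differed by at least 2-fold.

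Tet2, the gene named in the label, encodes an enzyme that oxidises methylated cytosine in DNA. Its transcript was not lower by the test in the arrays labelled knockdown. At 0 h the level was 92.8% of control (log2 difference -0.11 ± 0.10, adjusted p = 0.53), with a 95% interval from 78.1% to 110%. At 24 h it was 100% of control (0.01 ± 0.10, adjusted p = 0.98), with an interval from 84.5% to 119%. These values came from probe A_55_P2081303 on chromosome 3, positions 133126751 to 133126810. A nearby probe, A_55_P2051405 at 133126905 to 133126964, gave -0.28 (95% interval -0.62 to 0.05) at 0 h and 0.16 (-0.18 to 0.49) at 24 h. Another Tet2 probe, A_55_P2074075 at 133176421 to 133176479, was well above background on 4 of the 8 arrays and was not tested. On induction Tet2 rose 2.44-fold in control cells (adjusted p = 0.00012) and 2.64-fold in the line labelled knockdown (adjusted p = 7.5e-05), and the changes did not differ by the test (interaction 0.11 ± 0.14, adjusted p = 0.64). Every comparison between the lines below is therefore a comparison of labels, without a measured loss of the Tet2 transcript.

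**Figure D1:**
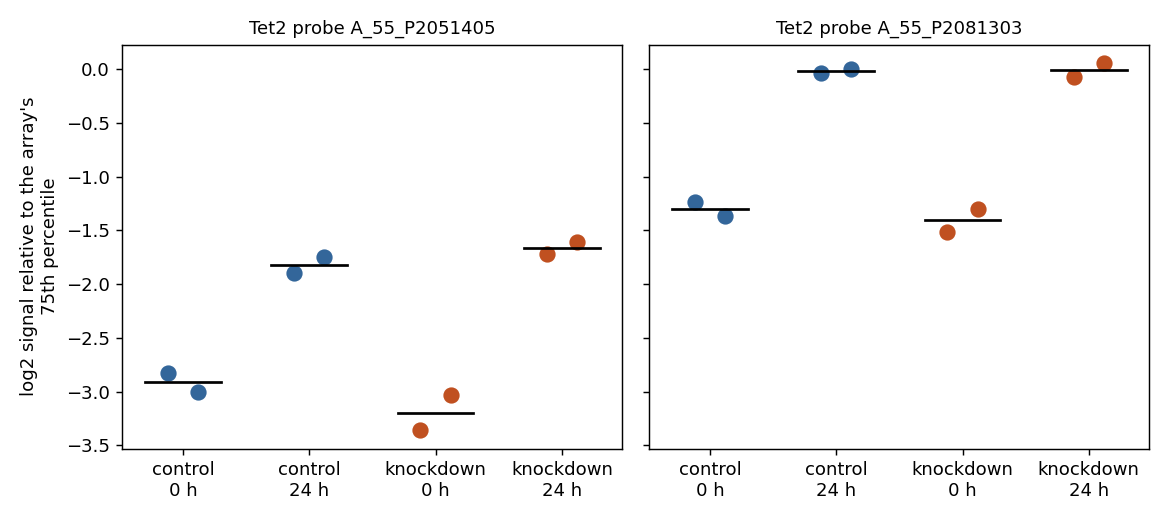
Tet2 signal on each array (log2 relative to the array's 75th percentile) for both kept probes, with a point per array and a line at the group mean of n = 2. For A_55_P2081303 the group means were -1.30 (control 0 h), -0.01 (control 24 h), -1.41 (labelled knockdown 0 h) and -0.01 (labelled knockdown 24 h).

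The control induction asked what 24 h of induction changed in pre-B cells. Estradiol was given together with IL-3 and M-CSF, so no change can be assigned to C/EBPα alone. Several myeloid genes rose by orders of magnitude. Cd14, a receptor for bacterial lipopolysaccharide on monocytes, rose 576-fold (log2 9.17 ± 0.11, n = 2 arrays per group), the chemokine Ccl2 rose 2786-fold (11.44 ± 0.20), and the macrophage pore protein gene Mpeg1 rose 134-fold (7.06 ± 0.09). Rag1 and Tk1 fell. Rag1, needed to rearrange antigen receptor genes, changed by -4.33 ± 0.06, and Tk1, which supplies thymidine for DNA synthesis, by -5.71 ± 0.05. The adjusted p values of these genes were at most 1.1e-06.

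Of the 36 tested myeloid surface receptors, 32 rose and none fell, with a median log2 change of 4.46, or 3.54 with dim genes at their bound. Lilrb4a, an inhibitory receptor of myeloid cells, was at least 689-fold higher and Cd33 at least 417-fold. Of 16 granule protein genes, 14 rose (median 5.16, at the bound 4.82), among them the antimicrobial peptide gene Camp at least 1248-fold, the collagenase gene Mmp8 at least 1028-fold and the calgranulin gene S100a8 at least 195-fold. Of 21 chemokine and cytokine genes, 16 rose (median 2.88), with Il1b at least 1223-fold and Ccl6 1020-fold. Of 26 myeloid transcription factor genes, 19 rose and 1 fell (median 1.66), with Fosl2 at 6.18 ± 0.09, Fos at 5.66 ± 0.10 and Cebpd, a relative of C/EBPα, at 5.06 ± 0.10. The remaining myeloid functions went the same way. In the lysosome list 19 of 32 rose and 1 fell, with the cathepsin genes Ctsc 26.5-fold and Ctsd 17.4-fold higher. In the NADPH oxidase complex, which makes superoxide, 5 of 6 rose, with Ncf1 33.9-fold higher and Cybb at 3.41 ± 0.13. In the adhesion list 22 of 33 rose, with S100a4 47.3-fold higher. The genes with the highest bounds were the interferon-inducible membrane protein genes Ifitm6, at least 4935-fold higher, and Ifitm1, at least 2576-fold.

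Of 22 B lineage transcription factor genes, 15 fell and 2 rose (median -1.64), with Bcl7a at -3.99 ± 0.07, Id3 at -3.74 ± 0.08, Bach2 at -3.43 ± 0.06 and Lef1 at -3.39 ± 0.05. In the pre-B receptor list 12 of 28 fell and 4 rose, with Rag2 at -5.01 ± 0.16, Dntt at -4.47 ± 0.09 and the interleukin 7 receptor gene Il7r at -2.82 ± 0.07. Of 29 S phase genes 28 fell (median -3.64), and of 29 G2 and M phase genes 28 fell (median -3.88), with the ribonucleotide reductase gene Rrm2 at -5.48 ± 0.10 and the mitotic genes Top2a at -4.82 ± 0.09 and Ccnb1 at -4.71 ± 0.07. In the list of cell cycle inhibitors and p53 targets 11 of 21 rose and 1 fell, with Cdkn1a 13.8-fold and Cdkn2b 8.56-fold higher. MYC and ribosome biogenesis genes fell in 18 of 29 cases and 1 rose, with Gnl3 at -2.01 ± 0.06. MHC class II presentation genes, which show antigen to T cells, rose in 5 of 8 cases, with Cd74 179-fold and H2-Eb1 11.5-fold higher. Interferon response genes rose in 19 of 33 cases and fell in 2 (median 1.47, at the bound 1.13), with Usp18 15.3-fold and Irf7 at least 14.7-fold higher.

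In glycolysis and hypoxia 14 of 27 rose and 1 fell, with the glucose transporter gene Slc2a1 at 2.06 ± 0.06. In lipid handling 8 of 20 rose and 1 fell, with the cholesterol exporter gene Abca1 16.5-fold and the triglyceride synthesis gene Dgat2 34.6-fold higher. In cholesterol synthesis 3 of 24 rose. In the unfolded protein list 12 of 22 rose, with Edem1 at 3.08 ± 0.08, and among NF-kappaB targets 10 of 19 rose, with Ptgs2 at least 44.2-fold. DNA methylation enzymes went both ways (8 higher and 7 lower of 28), with the maintenance enzyme gene Dnmt1 at -2.89 ± 0.09, its partner Uhrf1 at -3.87 ± 0.05 and Gadd45b at 3.76 ± 0.11. Among Polycomb and histone modifiers 6 of 31 fell and 2 rose, with Ezh2 at -2.46 ± 0.06. In the heat shock and oxidative stress list 2 rose and 5 fell of 19. Markers of other cell types moved in both directions, with 2 higher and 2 lower of 11 T cell markers, 2 and 4 of 10 erythroid and megakaryocyte markers, 3 and 2 of 10 dendritic markers, 2 and 1 of 10 stem and progenitor markers, and 3 and 0 of 6 stromal markers. The stromal gene Sparc, which macrophages also express, rose by 4.06 ± 0.14. Of 15 reference genes 2 rose and 1 fell, with Actb at 0.39 and Gapdh at 0.17, values that ranged from 0.28 to 0.45 and from 0.06 to 0.25 over the other scalings.

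In limma 2286 genes rose and 2123 fell, 27.3% of the genes tested, and 688 of the called genes had one group with no array well above background while 32 had neither group. Adjusted over the list alone, no list count changed. In camera 21 of the 29 lists differed from other genes with the preset correlation. With an estimated correlation 6 held, namely myeloid receptors (adjusted p = 0.0446), granule proteins (0.0446), myeloid transcription factors (0.0446), S phase (0.0446), chemokines (0.0469) and interferon response (0.0469). The other lists lost the call, with adjusted p = 0.0701 with an estimated correlation for G2 and M phase and for cell cycle inhibitors, 0.0961 for lysosome and for adhesion, 0.104 for MHC class II, 0.159 for MYC, 0.161 for NF-kappaB, and 0.165 for NADPH oxidase, pre-B receptor, lipid handling and glycolysis. It was adjusted p = 0.213 with an estimated correlation for the unfolded protein list, 0.283 for stromal markers, and 0.292 for B lineage factors and cholesterol synthesis. The lists without a call at either setting were DNA methylation (adjusted p = 0.438), Polycomb (0.135), heat shock (0.228), T cell (0.641), erythroid (0.347), dendritic (0.303), stem cell (0.582) and reference genes (0.641). The median and the mean had opposite signs for DNA methylation (-0.21 and 0.00), heat shock (-0.16 and 0.04) and T cell markers (0.09 and -0.14). The median of all genes shifted by -0.11 under median scaling.

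In the line labelled knockdown 31 of 36 myeloid surface receptors again rose on induction and all 29 S phase genes fell, and Tet2 was not lower in this line. Tyrobp, a signalling adaptor of myeloid receptors, rose 1066-fold (log2 10.06 ± 0.10, n = 2 arrays per group), the lysozyme gene Lyz2 rose 530-fold (9.05 ± 0.07), and Il1b was at least 698-fold higher. Rag1 changed by -4.68 ± 0.06, Dntt by -4.79 ± 0.09 and Rrm2 by -5.96 ± 0.10. Interferon response genes rose in 30 of 33 cases with a median of 3.45, among them Irf7 at least 104-fold, Usp18 121-fold and Rtp4 at least 67.5-fold. All 8 MHC class II genes rose, with Cd74 385-fold and H2-Eb1 34.1-fold higher.

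Of the myeloid surface receptors 31 of 36 rose and 1 fell (median 3.79, at the bound 3.54), of granule proteins 14 of 16 rose (5.74, at the bound 4.51), of chemokines 17 of 21 rose (3.21), of lysosome genes 26 of 32 rose and 1 fell, of NADPH oxidase genes 5 of 6 rose, of adhesion genes 23 of 33 rose, and of myeloid transcription factors 20 of 26 rose, with Cebpd 38.4-fold higher. In the B lineage list 15 of 22 fell and 2 rose, with Bcl7a at -3.41 ± 0.07, and in the pre-B list 7 of 28 fell and 3 rose. All 29 S phase genes and 28 of 29 G2 and M phase genes fell, with Tk1 at -5.87 ± 0.05 and Ccna2 at -5.23 ± 0.06. Cdkn1a rose 14.9-fold within a list in which 12 of 21 rose and 1 fell. Of MYC and ribosome biogenesis genes 22 of 29 fell and 1 rose, with Nolc1 at -2.45 ± 0.08. In glycolysis 18 of 27 rose and 2 fell, in lipid handling 11 of 20 rose and 1 fell, in the unfolded protein list 8 of 22 rose, in NF-kappaB targets 10 of 19 rose and 1 fell, and in cholesterol synthesis 2 of 24 rose. In heat shock and oxidative stress 8 of 19 fell and 2 rose, with the chaperone genes Hspd1 at -2.06 ± 0.06 and Hsph1 at -1.87 ± 0.07. DNA methylation enzymes counted 6 higher and 5 lower of 28, with Uhrf1 at -4.12 ± 0.05, and Polycomb genes 1 and 6 of 31, with Ezh2 at -2.38 ± 0.06. Marker lists counted 1 higher and 1 lower of 11 T cell markers, 2 and 4 of 10 erythroid, 6 and 1 of 10 dendritic, 4 and 1 of 10 stem cell and 3 and 0 of 6 stromal markers. Of 15 reference genes 2 rose and 1 fell, with a median of 0.53 (0.02 in control cells). The unadjusted p in limma was under 0.05 for 11 of them above 0 and 4 below. The mean of the list was 0.38, and 0.09 at the lowest over the scalings. Actb was at 0.80 and Gapdh at 0.61, neither called. These were the highest values over the scalings, and the lowest were 0.30 and 0.19.

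In limma 2700 genes rose and 2496 fell (32.2% of genes tested), and 576 of the called genes had one group with no array well above background while 7 had neither. The changes correlated with those of control cells across genes, which are not independent replicates, with r = 0.920. Of the called genes, 1995 rose in both inductions, where independent calls would share 382, and 1786 fell in both, where they would share 328. Calls from one fit are not independent. Only 1 gene rose in control cells and fell in the line labelled knockdown, and 7 did the reverse. Adjusted over the list alone, 1 more myeloid receptor gene and 1 more B lineage gene rose and 1 myeloid transcription factor gene fell. Camera called 21 lists, and the same 6 lists as in control cells held with an estimated correlation (adjusted p = 0.0383 to 0.0451). The others lost the call, with adjusted p = 0.0676 with an estimated correlation for G2 and M phase and cell cycle inhibitors, 0.0983 for lysosome, MHC class II, adhesion and MYC, 0.184 for glycolysis and NF-kappaB, 0.207 for NADPH oxidase and lipid handling, 0.271 for pre-B and stromal lists, 0.301 for B lineage and unfolded protein lists and 0.33 for heat shock. Lists without a call were DNA methylation (adjusted p = 0.455), Polycomb (0.0694), cholesterol synthesis (0.154), T cell (0.477), erythroid (0.65), dendritic (0.125), stem cell (0.205) and reference genes (0.205), and the erythroid median (0.34) and mean (0.13) lay above 0 while camera ranked the list as lower. Of these, Polycomb and dendritic lists were each called in 1 of the 5 other background and scaling settings. Median scaling moved the median of all genes from 0.14 to -0.11 and the split of calls to 2172 higher and 3385 lower.

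**Figure D2:**
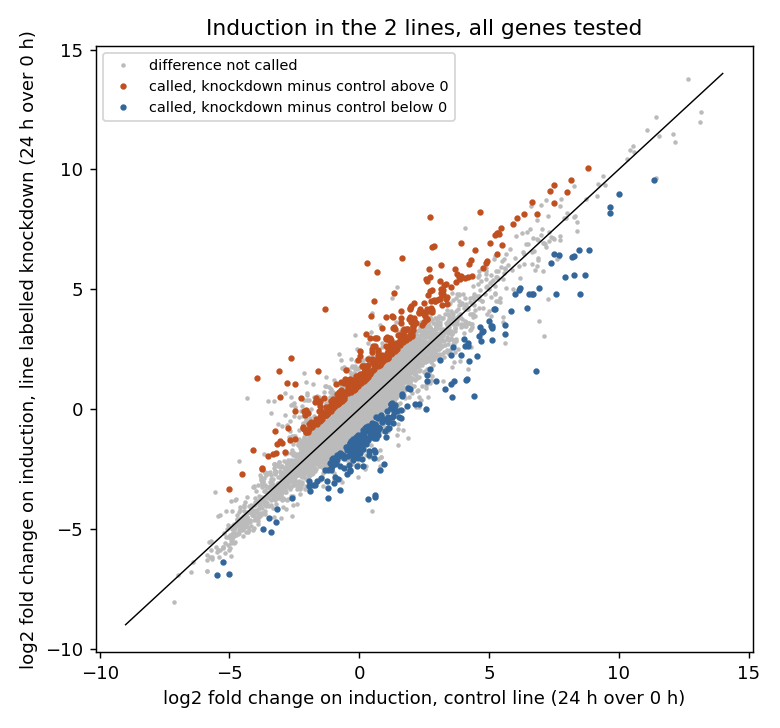
Each point is a gene, placed by its log2 fold change on induction in the control line (x axis) and in the line labelled knockdown (y axis), with n = 2 arrays per group and colours for genes whose difference was called. Across the 16152 genes r was 0.920, with 381 called differences above the diagonal and 237 below it.

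Before induction, the arrays labelled knockdown were compared with control arrays to ask what differed at the start, although Tet2 itself was not lower. Of the 278 genes that differed, 225 were lower, among them 8 of 21 chemokine and cytokine genes (adjusted p = 0.102 with an estimated correlation). Ebi3, a cytokine subunit of the interleukin 12 family, was at 11.2% of control (log2 -3.15 ± 0.08, n = 2 arrays per group, adjusted p = 0.00017). The growth factor gene Csf2 was at least 4.55-fold lower (adjusted p = 0.0011), Plin3, which coats lipid droplets, at least 11.7-fold lower (0.0017), and the chemokine gene Ccl4 differed by -2.36 ± 0.24 (0.0051) and the MHC class II chaperone gene Cd74 by -1.80 ± 0.17 (0.0046). Higher genes included Sema7a, a membrane-anchored semaphorin, at 3.46-fold (1.79 ± 0.09), the motor protein gene Myo5a at 2.86-fold (1.51 ± 0.07) and Gas7 at 2.96-fold (1.57 ± 0.08).

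Of 21 chemokine and cytokine genes 8 were lower and none higher (median -0.64, at the bound -0.39), with Ccl2 at least 1.72-fold lower and Ccl5 at -1.95 ± 0.25, measured on 1 of 2 arrays of the line labelled knockdown. In MHC class II 2 of 8 were lower, Cd74 and H2-Oa (-1.08 ± 0.12), and all 8 values lay below 0. In glycolysis and hypoxia 2 of 27 were lower, the lactate transporter gene Slc16a3 at -2.58 ± 0.14, measured on 1 of 2 arrays of the line labelled knockdown, and the phosphofructokinase gene Pfkl at -1.06 ± 0.07. In adhesion 2 of 33 were lower, among them S100a4 (-1.16 ± 0.06). In the interferon list 4 of 33 were lower, among them Oasl1 at -1.56 ± 0.06, Ifit3 at -1.30 ± 0.14 and Ifit1 at -2.42 ± 0.12, the last measured on 1 of 2 arrays of the line labelled knockdown, but the list was not called (adjusted p = 0.238), although it was called in 1 of the 5 other background and scaling settings. Myeloid receptors counted 2 lower of 36, Tyrobp at -1.02 ± 0.10 and Fcgr4 at least 1.45-fold, and granule proteins 1 of 16, Prtn3 at -1.14 ± 0.13. Stem cell markers counted 2 lower of 10, Egfl7 at -1.21 ± 0.09 and Ly6a at least 1.22-fold, T cell markers 1 of 11 (Cd2), dendritic markers 1 of 10 (Clec10a, dim in both groups), stromal markers 1 of 6 (Sparc, -1.97 ± 0.14) and NF-kappaB targets 1 of 19 (Ccl5). Called higher were 2 of 26 myeloid transcription factors, Bcl6 at 1.05 ± 0.07 and Bhlhe40 at 1.00 ± 0.07, 1 of 20 lipid genes (Cd36, 1.03 ± 0.18) against 1 lower (Pltp), 1 of 22 unfolded protein genes (Slc7a11) and 1 of 19 oxidative stress genes (Srxn1, 1.73 ± 0.17, measured on 1 of 2 control arrays).

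In limma 53 genes were higher and 225 lower (1.72% of genes tested), while 4954 had an unadjusted p under 0.05. Of the called genes, 67 had one group with no array well above background and 12 had neither, and of the 67 only 32 had a bound of at least 2-fold. Camera called 13 lists and none held with an estimated correlation. The lower lists were chemokines (adjusted p = 2.2e-09, adjusted p = 0.102 with an estimated correlation), glycolysis (2.3e-07 and 0.284), MHC class II (1.9e-05 and 0.265), adhesion (5.9e-05 and 0.284), granule proteins (0.0045 and 0.265), myeloid receptors (0.0053 and 0.284), lysosome (0.0055 and 0.348) and stem cell markers (0.0426 and 0.284, 0.0873 with the slide as a block, and 0.0025 to 0.350 over the alternatives). The higher lists were MYC (1.3e-05), cholesterol synthesis (2.7e-05), heat shock (2.7e-05), S phase (0.00019) and the unfolded protein list (0.0013), each with adjusted p = 0.284 with an estimated correlation, and the G2 and M phase list at 0.0576, which became 0.0356 with the block and ranged from 0.0026 to 0.477 over the alternatives. In limma no gene was called in the lysosome, NADPH oxidase, B lineage, pre-B, S phase, G2 and M phase, cell cycle inhibitor, MYC, DNA methylation, Polycomb, cholesterol, erythroid and reference lists, whose unadjusted p was under 0.05 for 13, 2, 8, 12, 15, 7, 13, 18, 12, 15, 13, 5 and 4 genes in that order. Camera did not call NADPH oxidase (adjusted p = 0.305), myeloid transcription factors (0.89), B lineage (0.882), pre-B (0.113), cell cycle inhibitors (0.882), DNA methylation (0.664), Polycomb (0.274), lipid handling (0.89), NF-kappaB (0.119), T cell (0.197), erythroid (0.285), dendritic (0.107), stromal (0.363) or reference genes (0.553). The median and mean had opposite signs for cell cycle inhibitors (0.06 and -0.03) and lipid handling (-0.02 and 0.01). Adjusted over the list alone, 1 adhesion gene was higher, and 2 dendritic and 4 stem cell markers were lower. Flt3, a cytokine receptor of progenitors, was at -1.06 ± 0.26 (adjusted p = 0.0535) and was called with the slide as a block (adjusted p = 0.046, and 0.0048 to 0.221 over the alternatives).

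Leaving out 1 of some arrays ended the call of Ccl5 (adjusted p up to 0.0653), Tyrobp (change down to -0.89), Prtn3 (-0.93), H2-Oa (-0.93), Bcl6 (0.99), Bhlhe40 (0.94), Cd36, Slc7a11 and Clec10a at 0 h, and without replicate 2 of the line labelled knockdown at 0 h the number of higher genes was 82. The normexp correction with percentile scaling left 6 genes higher and 93 lower, and Actb (-0.03, up to 0.09) and Gapdh (-0.12, up to 0.04) changed sign over the scalings.

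At 24 h the arrays labelled knockdown were compared with control arrays to ask what differed after induction, again without a lower Tet2 transcript. The interferon response list stood out. Of its 33 tested members, 25 were higher, none was lower, and all 33 values lay above 0 (median 1.76, at the bound 1.54). Ifit3, an antiviral protein gene, was 13.5-fold higher (log2 3.76 ± 0.14, n = 2 arrays per group, adjusted p = 0.00042), Ifit1 8.27-fold (3.05 ± 0.12), Usp18, which restrains interferon signalling, 7.61-fold (2.93 ± 0.12), and Mx1 at least 11.6-fold, with Rtp4 at 5.04 ± 0.22, measured on 1 of 2 control arrays. The interferon-inducible GTPase gene Tgtp2 was 9.55-fold higher (3.26 ± 0.05, adjusted p = 6.8e-05). Ifit1, Ifit3 and Tgtp2 have close relatives whose transcripts their probes were not shown to exclude. Among the lower genes were the calgranulin gene S100a8 at -4.30 ± 0.39 (adjusted p = 0.0040), the cytokine gene Tnfsf14 at -2.62 ± 0.08 (0.00042), the nucleotide receptor gene P2ry2 at -2.83 ± 0.23 (0.0029) and the chemokine genes Ccl7 at -2.15 ± 0.19 (0.0040) and Ccl6 at -1.58 ± 0.09 (0.0013).

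Of 21 chemokine and cytokine genes 5 were lower and none higher (median -0.52), including Ccl2 at -1.78 ± 0.20. Of 36 myeloid receptors 5 were lower and 1 higher, with Clec4d at -2.78 ± 0.29, Lilrb4a at -2.09 ± 0.19, and Msr1 at -1.84 ± 0.19 and Clec4e at -1.82 ± 0.24, both measured on 1 of 2 arrays of the line labelled knockdown. Of 16 granule genes 4 were lower, S100a8, Mmp8 (-1.26 ± 0.22), Mmp9 (-1.25 ± 0.22) and Fcnb (-1.23 ± 0.23). Of 26 myeloid transcription factors 2 were lower, Bhlhe40 at -1.49 ± 0.07 and Tfec at -1.01 ± 0.07. Single calls were Anxa2 (-1.42 ± 0.14) among 33 adhesion genes, the cyclin gene Ccne1 (-1.09 ± 0.07) among 29 S phase genes, the apoptosis gene Pmaip1 (1.03 ± 0.07) among 21 cell cycle inhibitors and p53 targets, H2-Eb1 (1.04 ± 0.08) among 8 MHC class II genes, Slc7a11 (-1.17 ± 0.23) among 22 unfolded protein genes and Pdgfrb (-1.17 ± 0.21) among 6 stromal markers. Flt3 (1.28 ± 0.26) was higher and Cd80 (-1.21 ± 0.26) lower among 10 dendritic markers, Flt3 alone was called among 10 stem cell markers, and Bcl3 (-1.14 ± 0.21) and Ccl5 (-1.09 ± 0.25) were lower among 19 NF-kappaB targets. Wfdc21 was at least 3.18-fold lower and Plin3 was at -2.79 ± 0.23.

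In limma 168 genes were higher and 161 lower (2.04% of genes tested), and 25 of the 168 were interferon list members. Of the list's 22 members well above background on all 8 arrays, 15 were higher. Of the called genes 63 had one group with no array well above background, 24 of these with a bound of at least 2-fold, and 17 had neither group. In camera the interferon list had adjusted p = 1.0e-31, and adjusted p = 0.00964 with an estimated correlation, the only list that held. Adjusted over the list alone, 26 interferon genes were higher and no other count changed. The 11 other lists called with the preset correlation lost the call. The lower lists were chemokines (3.7e-08, and adjusted p = 0.0706 with an estimated correlation), G2 and M phase (8.5e-05 and 0.367), S phase (0.00135 and 0.36), MYC (0.0039 and 0.391), adhesion (0.0061 and 0.391), myeloid receptors (0.0067 and 0.343) and glycolysis (0.0332 and 0.585). The higher lists were B lineage factors (0.00085 and 0.392), dendritic markers (0.0147 and 0.343), cell cycle inhibitors (0.0148 and 0.343) and MHC class II (0.0366 and 0.372, 0.056 with the slide as a block, and 0.0031 to 0.372 over the alternatives). In limma no gene was called in the lysosome, NADPH oxidase, B lineage, pre-B, G2 and M phase, MYC, DNA methylation, Polycomb, cholesterol, lipid, glycolysis, heat shock, T cell, erythroid and reference lists, whose unadjusted p was under 0.05 for 17, 1, 11, 14, 17, 8, 11, 9, 8, 11, 13, 8, 5, 4 and 6 genes in that order. Camera did not call granule proteins (adjusted p = 0.163), lysosome (0.302), NADPH oxidase (0.769), myeloid transcription factors (0.0975), pre-B (0.63), DNA methylation (0.904), Polycomb (0.346), cholesterol (0.385), lipid (0.0835), the unfolded protein list (0.769), heat shock (0.0835), NF-kappaB (0.488), T cell (0.0835), erythroid (0.724), stem cell (0.617), stromal (0.534) or reference genes (0.302). Of these, granule proteins were called in 5 of the 5 other background and scaling settings (mean -0.39 to -0.55), heat shock in 4, myeloid transcription factors in 2, and lipid handling and T cell markers in 1 each. The median was above 0 and the mean below for DNA methylation (0.00 and -0.01), the unfolded protein list (0.02 and -0.03), NF-kappaB (0.04 and -0.03) and stromal markers (0.17 and -0.07), and camera ranked erythroid markers as lower with both above 0 (0.02 and 0.01).

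Leaving out 1 of some arrays ended the call of Ccl2 (adjusted p up to 0.0520), H2-Eb1 (change down to 0.99), Pmaip1 (0.99), Ccl5, Clec4e, Mmp8, Mmp9, Fcnb, Tfec, Slc7a11, Bcl3, Flt3, Cd80 and Pdgfrb at 24 h. The normexp correction with percentile scaling left 90 genes higher and 64 lower, and Actb (0.38, from -0.07) and Gapdh (0.32, from -0.02) changed sign over the scalings.

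**Figure D3:**
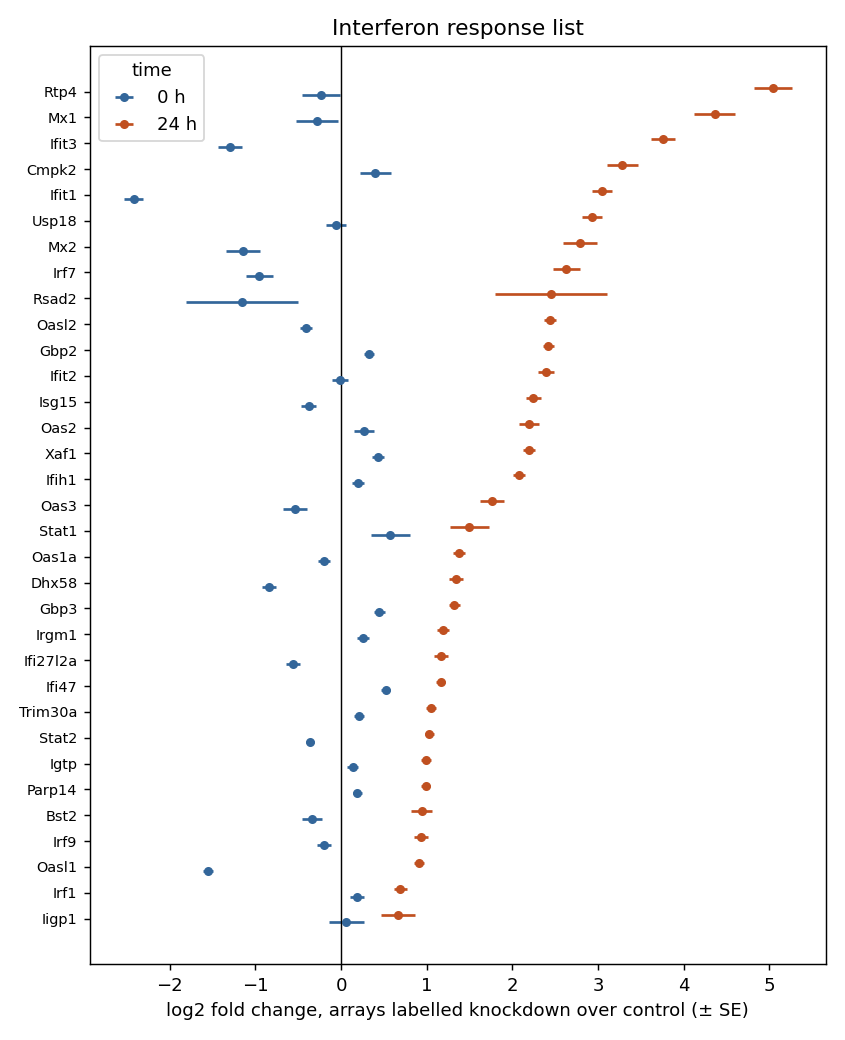
Log2 fold change of each tested interferon list member in arrays labelled knockdown over control arrays (x axis, ± SE, n = 2 arrays per group) at 0 h and at 24 h, with fitted values for dim genes. All 33 values lay above 0 at 24 h, and 14 of 33 did at 0 h.

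The interaction asked whether induction changed a gene by a different amount in the line labelled knockdown than in control cells. Several interferon genes had a difference above 0. Ifit3 changed by 0.67 in control cells and by 5.72 in the line labelled knockdown, a difference of 5.05 ± 0.19 (n = 2 arrays per group, adjusted p = 0.0013). The difference was 5.47 ± 0.16 for Ifit1 (0.00076), 3.50 ± 0.07 for Tgtp2 (0.00031) and 2.99 ± 0.17 for Usp18 (0.0022). Ifit1 fell in control cells, from a log2 level of -2.79 to -4.10. In the line labelled knockdown Ifit1 rose from -5.21, measured on 1 of 2 arrays, to -1.05. Several genes induced in control cells gained less. Bhlhe40, a transcriptional repressor, changed by 3.65 in control cells and by 1.16 in the line labelled knockdown (difference -2.49 ± 0.10, adjusted p = 0.0013), Dgat2 by 5.11 and 3.39 (-1.72 ± 0.19, 0.0083), and Fosl2 by 6.18 and 5.06 (-1.12 ± 0.13, 0.0090).

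In the interferon list 23 of 33 members had a called difference above 0 and none below (median 1.93). In MHC class II 3 of 8 lay above 0, H2-Eb1 (1.56 ± 0.12), H2-Oa (1.31 ± 0.17) and Cd74 (1.10 ± 0.24). Cd74 started lower in the line labelled knockdown, at a log2 level of -3.09 against -1.29 in control cells at 0 h. At 24 h Cd74 was at -0.70 ± 0.17 against control (adjusted p = 0.0522 in limma), while the other 7 values of the list lay above 0. Myeloid receptors divided into 3 above and 4 below 0 of 36, granule genes into 3 and 1 of 16, chemokines into 3 and 2 of 21 and myeloid transcription factors into 1 and 4 of 26, with Klf2 at 1.59 ± 0.10 and Fosl2 at -1.12 ± 0.13. Dendritic markers counted 4 above and 1 below of 10, with Batf3 at 1.51 ± 0.12, stem cell markers 2 and 0 of 10, T cell markers 2 and 0 of 11, with Zap70 at 1.48 ± 0.09, and erythroid markers 2 and 1 of 10, with the transferrin receptor gene Tfrc at -1.36 ± 0.09. The cell cycle inhibitor list counted 2 above 0, Pmaip1 and Trp53inp1. Lipid handling counted 1 above and 3 below of 20, with Dgat2 at -1.72 ± 0.19, the unfolded protein list 2 below of 22, oxidative stress 1 below of 19 (Srxn1, -2.23 ± 0.24), S phase 1 below of 29 (Ccne1, -1.45 ± 0.09), MYC 1 below of 29 (Utp20), adhesion 1 above and 1 below (Anxa2, fitted value -2.41 ± 0.19, not well above background at 0 h) of 33. Single members lay above 0 in the B lineage (Id3, 1.29 ± 0.11), lysosome (Grn, 1.20 ± 0.07), glycolysis (Slc16a3, 2.10 ± 0.20) and stromal (Sparc, 1.41 ± 0.19) lists. Slc16a3 and Sparc were lower at 0 h in the line labelled knockdown and were not called higher at 24 h. Srxn1 was higher at 0 h in that line and was not called lower at 24 h.

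In limma 381 genes had a called difference above 0 and 237 below (3.83% of genes tested). Of these, 99 and 84 had a group with no array well above background, and 259 and 105 were well above background on all 8 arrays. Among the 2286 genes that rose in control cells, 160 had a difference above 0 and 92 below. Among the 2123 that fell, 80 lay above 0 and 27 below. The median difference was 0.05 over the control-induced genes and -0.06 over the control-repressed genes. The median of all genes was also 0.05, and with median scaling the medians of the control-induced genes and of all genes moved to -0.10 and -0.09, so under that setting the change of sign was shared by all genes. In camera the interferon list had adjusted p = 4.1e-26, and adjusted p = 0.0141 with an estimated correlation, and no other list held. The lists above 0 with the preset correlation were MHC class II (1.9e-05, and adjusted p = 0.257 with an estimated correlation), glycolysis (0.0046 and 0.462), dendritic markers (0.0090 and 0.257), B lineage factors (0.0090 and 0.472), cell cycle inhibitors (0.0228 and 0.306, 0.0653 with the slide as a block, and 0.0018 to 0.306 over the alternatives) and stem cell markers (0.0328 and 0.306, 0.099 with the block, and 0.0018 to 0.361 over the alternatives). Those below 0 were MYC (4.8e-07 and 0.306), S phase (2.0e-06 and 0.257), G2 and M phase (1.9e-05 and 0.306), heat shock (4.8e-05 and 0.392), cholesterol synthesis (0.0176 and 0.472) and the unfolded protein list (0.0313 and 0.462, 0.0975 with the block, and 0.0028 to 0.462 over the alternatives). In limma no gene was called in the NADPH oxidase, pre-B, G2 and M phase, DNA methylation, Polycomb, cholesterol, NF-kappaB and reference lists, whose unadjusted p was under 0.05 for 1, 15, 11, 10, 14, 10, 4 and 5 genes in that order. Camera did not call myeloid receptors (adjusted p = 0.51), granule proteins (0.841), lysosome (0.0558), NADPH oxidase (0.303), myeloid transcription factors (0.219), pre-B (0.149), chemokines (0.185), adhesion (0.259), DNA methylation (0.752), Polycomb (0.145), lipid (0.219), NF-kappaB (0.713), T cell (0.0731), erythroid (0.4), stromal (0.713) or reference genes (0.155), and the granule list had a median of 0.11 and a mean of -0.09. Of these, T cell markers were called in 4 of the 5 other background and scaling settings, lysosome in 3 and myeloid receptors in 1. Adjusted over the list alone, the counts rose to 24 interferon genes and 4 myeloid receptors above 0, and to 2 granule genes and 3 chemokines below 0.

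Leaving out 1 array lowered the count below 0 to 150 (control 0 h replicate 1), 135 (control 24 h replicate 1), 154 (control 24 h replicate 2) and 155 (labelled knockdown 24 h replicate 2). Among control-induced genes, the count below 0 was 51, 57, 57 and 47 without control 24 h replicate 1 or 2 or labelled knockdown 24 h replicate 1 or 2, and the count above 0 was 99 without control 24 h replicate 2. Leaving out 1 of some arrays also ended the calls of Cd74 (adjusted p up to 0.106), Utp20 (0.0592) and Sparc (0.0525). Median scaling gave 103 above 0 and 110 below, and normexp with percentile scaling 209 and 73. Actb (0.41, from -0.15) and Gapdh (0.44, from -0.06) changed sign over the scalings.

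**Figure D4:**
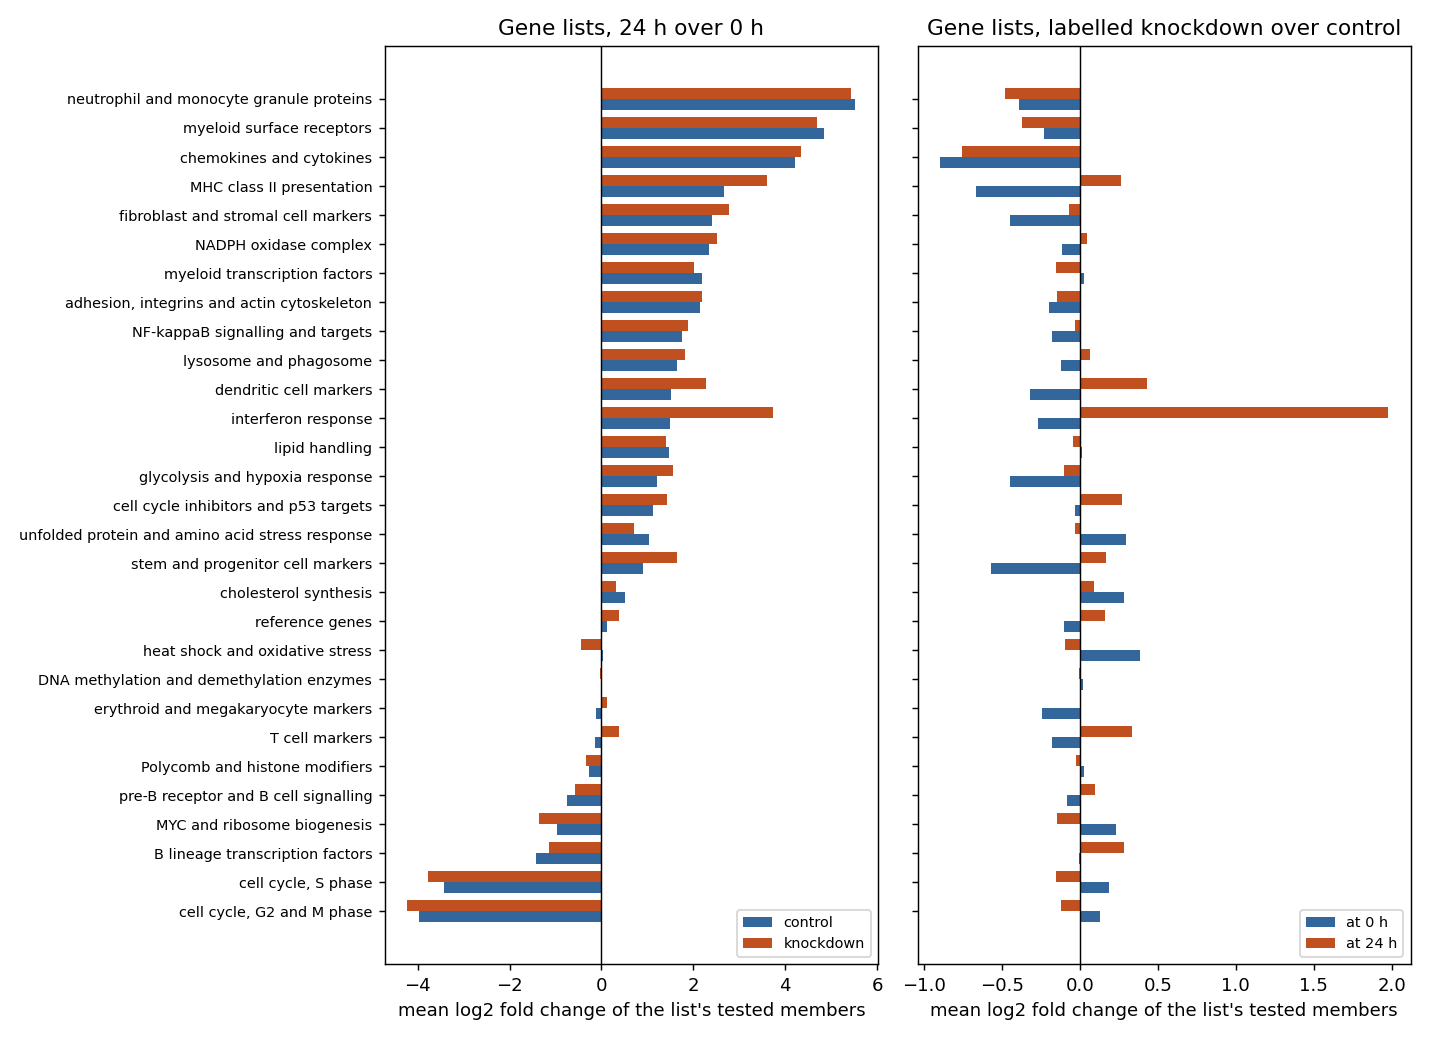
Mean log2 fold change of the tested members of each gene list, for both inductions (left, 24 h over 0 h) and for arrays labelled knockdown over control arrays at 0 h and 24 h (right), with n = 2 arrays per group and fitted values for dim genes. The interferon list had means of -0.27 at 0 h and 1.98 at 24 h.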

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

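The test of a standing response before induction was chosen only after the result had been seen, and the tests of scaling and of slides were chosen before. The genes and lists below are here because their log2 change on induction differed between the line labelled knockdown and the control line by the interaction test in limma or camera. Tet2 itself was not lower in the arrays labelled knockdown. Values are the change in the line labelled knockdown minus the change in control cells, with n = 2 arrays per group, and values of genes with a group in which no array was well above background are fitted values. These genes were Irf7, Acnat1, Mx2, H2-T24, Mx1, Ifit1bl1, Rtp4, Ifit3b, P2ry2, Sftpb, Eid3, S100a8, Rgcc, Wfdc21, Ltb4r1, Tnfsf14, Clec4d, Lilrb4a, Msr1, Tfec, Ccl7, Anxa2, Pltp, Slc7a11, Clec10a, Ly6a, Tgm1 and Oas1g. A value above 0 need not mean a higher level at 24 h. Called lower at 0 h in the arrays labelled knockdown were Cd74, H2-Oa, Ebi3, Ccl4, Slc16a3, Sparc, Pltp, Clec10a, Ly6a and Cd2. None of them was called higher at 24 h, and Clec10a was dim in both groups at 0 h.

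Some of the calls ended when 1 array was left out. The number of arrays that ended a call when left out was 8 for Cd74, 7 for H2-T24, Orm2, Eid3, Lyz1, Nfe2 and Cd80, and 6 for S100a8, Ltb4r1, Clec4d, Ccl4, Cd36, Flt3 and Clec10a. The number was 5 for Msr1, Ccl7, Ly6a and Tgm1, 4 for Lilrb4a, Utp20 and Oas1g, 3 for Creld2 and Sparc, 2 for Lyz2 and Sult1a1, and 1 for Tfec and Slc7a11. The highest adjusted p without 1 array was 0.137 (Eid3).

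Of the 33 tested interferon response genes, 23 had a called difference above 0, and all 33 values lay above 0 (adjusted p = 0.0141 with an estimated correlation). Antiviral genes of the Ifit family stood at 5.78 (Ifit3b), 5.47 (Ifit1), 5.05 (Ifit3) and 4.67 (Ifit1bl1), although Ifit3 and Ifit3b, and Ifit1 and Ifit1bl1, are close relatives whose signals were not separated. Rtp4 was at 5.28, the antiviral GTPase genes Mx1 at 4.64 and Mx2 at 3.93, and the transcription factor Irf7, which amplifies interferon production, at 3.58. Tgtp2 was at 3.50, Usp18 at 2.99, Oasl2 at 2.85 and Oas1g at 2.82, and Tgtp2 and Oas1g also have close relatives. The nonclassical MHC gene H2-T24 was at 3.96, the acyltransferase gene Acnat1 at 3.89, the sulfotransferase gene Sult1a1 at 3.16 and Csprs at 2.73. The mean over the interferon list was 2.24.

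Of 8 MHC class II genes 3 had a called difference above 0, and of 10 dendritic markers 4 lay above and 1 below (adjusted p = 0.257 with an estimated correlation for each list). H2-Eb1 was at 1.56, H2-Oa at 1.31 and Cd74 at 1.10 (list mean 0.93), and among dendritic markers (mean 0.75, down to 0.39 over the scalings) the growth factor receptor Flt3 was at 2.34, Clec10a at 1.80 and Batf3 at 1.51, while the costimulatory Cd80 was at -1.74. Stem and progenitor markers had a mean of 0.74 with Ly6a at 2.18, but the mean was as low as 0.26 over the scalings and the list was called in 1 of 5 other background and scaling settings. In the lymphoid lists Zap70 was at 1.48, Id3 at 1.29 and Cd2 at 1.17, with a mean of 0.29 over B lineage factors (down to 0.15 over the scalings). Among erythroid markers, Gp9 was at 1.23, Nfe2 at 1.21 and the transferrin receptor Tfrc at -1.36. The stromal gene Sparc was at 1.41.

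Other genes went both ways. Below 0 were S100a8 (-3.11), P2ry2 (-3.72), Ltb4r1 (-2.80), Tnfsf14 (-2.69), Clec4d (-2.23), Ccl7 (-1.87), Lilrb4a (-1.80) and Msr1 (-1.57), and the regulators Bhlhe40 (-2.49), Fosl2 (-1.12) and Tfec (-1.06). Above 0 were the lysozyme genes Lyz1 (1.19) and Lyz2 (1.05), whose signals were not separated, the protease inhibitor Serpinb1a (1.13), the growth factor Grn (1.20), the transcription factor Klf2 (1.59), and the cytokine genes Ebi3 (1.87) and Ccl4 (1.84). Ebi3 and Ccl4 were lower at 0 h in the arrays labelled knockdown, and no chemokine or cytokine gene was called higher at 24 h. The membrane-binding protein Anxa2 was at -2.41. Further values below 0 were Orm2 (-5.21), Sftpb (-3.36), Eid3 (-3.27), Rgcc (-2.91), Wfdc21 (-2.87) and Tgm1 (-2.47). A value below 0 need not mean a lower level at 24 h. Orm2, Srxn1 and Cd36 were called higher at 0 h in the arrays labelled knockdown. Srxn1 and Cd36 were not called lower at 24 h.

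List means were -0.34 for S phase with Ccne1 at -1.45, -0.25 for G2 and M phase (down to -0.39 over the scalings), -0.38 for MYC and ribosome biogenesis with Utp20 at -1.11, and 0.30 for cell cycle inhibitors and p53 targets (down to 0.15) with Pmaip1 at 1.31 and Trp53inp1 at 1.14. The means were -0.48 for heat shock and oxidative stress with Srxn1 at -2.23, -0.33 for the unfolded protein list with the cystine transporter Slc7a11 at -2.47 and Creld2 at -1.03, and -0.19 for cholesterol synthesis (down to -0.33). Glycolysis had a mean of 0.35 (down to 0.16) with the lactate transporter Slc16a3 at 2.10. Among lipid genes, Pltp was at 2.08, Dgat2 at -1.72 and Cd36 at -1.25. These list calls, unlike that of the interferon list, were lost with an estimated correlation, and so were those of the B lineage, MHC class II, dendritic and stem cell lists, with adjusted p = 0.257 to 0.472 with an estimated correlation.

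The pattern weighed here is the higher level of interferon response genes in the arrays labelled knockdown at 24 h, with a mean log2 difference of 1.98. The scaling of the arrays is argued against, since the lowest mean over the 5 other background and scaling settings was 1.58. The mean was 1.97 on one slide and 1.98 on the other, so the difference did not rest on a single slide. The test of slides decides no more than that, since every group was on both slides and a shift of a whole slide cancels. A standing response of the list as a whole before induction is argued against by a mean of -0.27 at 0 h, with 4 members called lower and none higher. The unadjusted p in limma was under 0.05 for 9 members above 0 and 13 below. A small standing difference in some members therefore stays open. A difference between single cultures stays open, because the arrays of a group are technical duplicates, as do an effect of the hairpin itself and an effect of Tet2, none of which was tested. A response to interferon that arose with induction in this culture is a candidate explanation that was not tested, without a link to Tet2, whose transcript was not lower.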

How the results depend on the processing

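The floor on dim signals and the counts outside the interferon list were chosen only after the data had been seen, and every other alternative was chosen before. The tables do not show which of the mechanisms behind a change of processing moved a value, so unless a reason is given the cause was not tested. Pairs of counts are genes higher and lower in the arrays labelled knockdown, or genes with an interaction above and below 0, in that order.

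Both inductions were stable. Their counts stayed within 1.5 times under each background, scaling, filter and moderation alternative, and moved beyond that only where the fold minimum changed. With adjusted p alone the counts were 4964 and 5027 in control cells and 5851 and 5166 in the line labelled knockdown, with a fold minimum of 1.5 they were 3535 and 3518, and 4150 and 3858, and with a minimum of 3 they were 1263 and 1130, and 1531 and 1283. These shifts follow from the fold minimum itself. Leaving out 1 array gave 2250 to 2305 and 2047 to 2131 in control cells, and 2587 to 2754 and 2351 to 2504 in the line labelled knockdown. Of 125 called named genes in each induction, 2 lost the call in at least 1 of the fits without 1 array (Cd4 and Itgb3 in control cells, Cd4 and Cd5 in the line labelled knockdown), and 3 and 5 in at least 1 background or scaling setting.

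The comparisons between lines depended more on the processing. At 0 h, where 53 genes were higher and 225 lower, normexp with percentile scaling gave 6 and 93, normexp with quantile normalization 9 and 84, the values as deposited 10 and 84, and the filter on all 8 arrays 22 and 135, the last with fewer genes tested. Of the 278 genes called at 0 h, 96 were also called with normexp and percentile scaling and 92 with the value table. At 24 h, where 168 were higher and 161 lower, the same settings gave 90 and 64, 90 and 75, 88 and 75, and 94 and 53, with 141 and 149 of the 329 reported genes also called with normexp and percentile scaling and with the value table, and no filter on dim probes gave 105 and 82. For the interaction, 381 and 237 became 209 and 73 with normexp and percentile scaling, 184 and 108 with normexp and quantile normalization, 179 and 110 with the value table, 103 and 110 with median scaling, and 95 and 26 without a filter, and 109 lay below 0 with the filter on all 8 arrays. Of the 618 reported genes, 253, 258, 212 and 120 were also called with normexp and percentile scaling, the value table, median scaling and no filter.

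Tests and thresholds moved these counts by construction. In the order 0 h, 24 h and interaction, adjusted p alone gave 957 and 1221, 1194 and 1042, and 1489 and 1142. A fold minimum of 1.5 gave 237 and 586, 467 and 423, and 1014 and 612. A fold minimum of 3 gave 14 and 87, 55 and 47, and 131 and 95. Limma treat against 1.5-fold gave 18 and 116, 72 and 52, and 124 and 41. Without a test, at 2-fold, slide 1 alone gave 314 and 447, 389 and 383, and 888 and 662, slide 2 alone gave 181 and 506, 359 and 387, and 814 and 471, and averaged duplicates gave 161 and 389, 297 and 275, and 725 and 457. Leaving out 1 array gave 38 to 82 and 201 to 219 at 0 h, 127 to 171 and 108 to 166 at 24 h, and 258 to 381 and 135 to 272 for the interaction. The 82 came without replicate 2 of the line labelled knockdown at 0 h, and the lower interaction counts of 150, 135, 154 and 155 came without control 0 h replicate 1, control 24 h replicate 1, control 24 h replicate 2 and labelled knockdown 24 h replicate 2. Outside the interferon list, 143 genes were higher and 161 lower at 24 h, and 358 and 237 had an interaction above and below 0.

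Among genes induced in control cells, 160 had an interaction above 0 and 92 below. These counts were 82 and 50 with normexp and percentile scaling, 52 and 47 with median scaling, 55 and 11 without a filter, 105 and 36 with the filter on all 8 arrays, 666 and 456 with adjusted p alone, 398 and 227 and 60 and 41 with fold minimums of 1.5 and 3, and 71 and 16 with treat. The count above 0 was 78 with normexp and quantile normalization and 78 with the value table, and the count below 0 was 256 and 182 on slides 1 and 2 alone and 167 with averaged duplicates. Leaving out 1 array gave 99 to 177 above 0 and 47 to 103 below, with 99 without control 24 h replicate 2, and with 51, 57, 57 and 47 below 0 without control 24 h replicate 1, control 24 h replicate 2, labelled knockdown 24 h replicate 1 and labelled knockdown 24 h replicate 2.

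The median interaction of control-induced genes was 0.0493 and that of all genes 0.0495, and all genes were at -0.0944 with median scaling and 0.0995 with normexp and percentile scaling. For control-induced genes it was 0.0226 and -0.00594 with the normexp settings (percentile, quantile), -0.0152 with the value table, 0.0051 with quantile normalization, -0.105 with median scaling, 0.0236 and 0.0205 on slides 1 and 2 alone, and 0.0752 with genes chosen on slide 2 and measured on slide 1. Leaving out 1 array gave 0.022 to 0.056. The median of control-repressed genes, -0.0633, stayed below 0. It was -0.0363 and -0.0975 with the normexp settings, -0.102 with the value table, -0.0842 with quantile normalization, -0.192 with median scaling, -0.0558 without a filter, -0.0903 with the filter on all 8 arrays, -0.0921 with the floor on dim signals, -0.0113 and -0.0381 on slides 1 and 2 alone, and -0.0502 with averaged duplicates. With genes chosen on one slide and measured on the other it was -0.0686 and -0.0773, with adjusted p alone -0.0315, with fold minimums of 1.5 and 3 -0.0433 and -0.0804, and with treat -0.0574. Leaving out 1 array gave -0.075 to -0.020.

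Tet2 at 0 h was -0.28 on slide 1 alone and 0.0647 on slide 2 alone, and -0.22 to -0.00053 without 1 array. E2f7, at least 63.5-fold lower on induction in the line labelled knockdown, was at 0.26 with the filter on all 8 arrays, where another probe stood for the gene. Named genes with a called difference between the lines lost the call in at least 1 fit without 1 array in 19 of 45 cases at 0 h, 15 of 41 at 24 h and 27 of 68 for the interaction, and in at least 1 background or scaling setting in 29, 17 and 33 cases. No named result changed direction without 1 array. No list with a camera call changed sign under the 5 other background and scaling settings. The calls not kept in all 5 were pre-B and unfolded protein in the induction of the line labelled knockdown, myeloid receptors, lysosome and stem cell at 0 h, MHC class II and glycolysis at 24 h, and B lineage, cell cycle inhibitors and stem cell in the interaction. Calls gained in some of the 5 were granule proteins (5), heat shock (4), myeloid transcription factors (2), lipid handling (1) and T cell (1) at 24 h, T cell (4), lysosome (3) and myeloid receptors (1) in the interaction, G2 and M phase (2) and interferon (1) at 0 h, and Polycomb (1) and dendritic (1) in the induction of the line labelled knockdown, and the mean of each of these lists kept its sign in all 5. Camera calls of the interferon list at 24 h and in the interaction held in each of the 21 alternatives with a camera test. Among these, the trend and robust setting does not enter camera, so it could not have changed a list call. The limit from signal over background is that 47.4% to 55.6% of probe spots per array were well above background, so low genes enter only as bounds or fitted values.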

Other observations

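The 3 Tet2 tests and the reading of abundant genes with a low level in the other line were chosen only after the result had been seen, and the test on the other slide and the planned share test were chosen before. Of the 381 genes with an interaction above 0, 148 were called at neither time when the lines were compared, 118 were lower at 0 h only and 104 were higher at 24 h only in the arrays labelled knockdown. Of the 237 below 0, 114 were called at neither time, 99 were lower at 24 h only and 19 were higher at 0 h only. The differences at 0 h and at 24 h were nearly unrelated across genes (r = 0.0588). The calls shared 20 genes lower at both times, where independent calls would share 2.24, and 14 higher at both times (0.551). In opposite directions, 5 were higher at 0 h and lower at 24 h (0.528), and 6 lower at 0 h and higher at 24 h (2.34). Both comparisons came from one fit with one estimate of each gene's spread, so the calls are not independent and no excess is claimed.

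Of the 161 genes lower at 24 h, 93 were induced in control cells, and of the 168 higher, 70 were induced and 39 repressed. Independent calls would share 22.8, 23.8 and 22.1 genes, but these comparisons use the same control arrays at 24 h, so the calls are not independent and no excess is claimed.

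The Tet2 transcript was not lower in the arrays labelled knockdown, by either kept probe. An exchange of line labels with a knockdown of over 0.5 log2 is argued against, since the highest upper 95% limit of the difference was 0.49, near the limit of 0.5 set for that test, but at 24 h the lower limits of -0.24 and -0.18 exclude such a knockdown under the given labels as well. Probes with a flat signal are argued against, since the lowest 95% limit of the rise on induction was 0.76. That rise does not show that the signal followed the Tet2 transcript alone, because no probe sequences were searched. A loss of another part of the transcript stays open, because the remaining probe was well above background on only 4 arrays, and so do a knockdown weak enough to lie within the intervals and a loss of protein alone, each with the labels as given or exchanged. No biological explanation was tested.

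Of the 225 genes lower before induction in the arrays labelled knockdown, 47.6% were induced in control cells, 3.36 times the number that independent calls would share, while 48 were repressed in control cells where 29.6 would be. These calls come from one fit and share the control 0 h arrays, so they are not independent. Noise that raised genes in the control 0 h arrays would make them look repressed on induction, against this overlap, and it is argued against, since genes chosen on one slide had medians of -1.22 and -1.28 on the other. The planned test of already induced cells in the control culture gave 18% of 100 abundant genes below the level needed and could not have passed its limit of 50%, because only 21 of the 100 had a low enough level in the other line. Another set was read, the 15 genes with a low enough level for the smaller share that 75% of the pattern's genes would need. Of these, 12 (80%) lay below the level that share gives. This argues against cells with the full control profile at 24 h as the source for that 75%. A smaller share stays open for the other genes of the pattern. Both readings took induced cells to have that full profile, so partly induced cells stay open. A difference between single cultures, in clonal origin or growth state, may also explain the pattern and cannot be told apart from the label in this design.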
